A study of Mus musculus with 4 samples.

How the data were processed

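RNA from the hippocampus of ovariectomized C57BL/6 mice was sequenced as 50-base single reads from bar-coded TruSeq RNA libraries, per the labels' protocols. The 4 libraries fall into 2 genotypes, FLOXED and PELP1 FBKO, with 2 libraries each. All animals carried estradiol (E2) mini pumps, underwent global cerebral ischemia and were killed after 24 h of reperfusion, per the labels' protocols. The genotype of each library came from its label, and the libraries are named by genotype and replicate number.

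The deposited files hold raw read counts per gene symbol, with no normalization by the authors, as the whole numbers and unequal totals of the files show. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.8b and HTSeq, and the mm9 mouse build. The series text names a human build instead, but the files hold mouse gene symbols. The HTSeq version, its strand and overlap settings and the gene annotation were not given in the sources used here. The series text also states that sequencing was run in duplicate with the reads combined. Nothing says whether the 2 libraries of a genotype came from separate animals, so p-values measure only the spread between these samples, which may be technical.

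Each file listed 22609 genes, of which 18464 had a read in at least 1 library. Reads assigned to genes came to 17524594 in FLOXED 1, 21921862 in FLOXED 2, 22447658 in PELP1 FBKO 1 and 19882952 in PELP1 FBKO 2. HTSeq's summary rows stayed out of library sizes and tests. Of the uniquely placed reads, 15.7%, 15.0%, 14.7% and 14.9% lay in no gene, in that order, and about 1% were ambiguous between genes. Alignments that were not unique made up 47.7% of all rows in FLOXED 1, 40.4% in FLOXED 2, 38.5% in PELP1 FBKO 1 and 41.5% in PELP1 FBKO 2. Such reads were not counted, so levels of genes with near-identical copies, such as ribosomal protein genes with many pseudogenes, are uncertain. The 10 most abundant genes took between 2.85% and 3.30% of gene reads. A gene with 0 reads could have a level of up to 0.171 CPM (counts scaled to library size) in FLOXED 1, 0.137 in FLOXED 2, 0.134 in PELP1 FBKO 1 and 0.151 in PELP1 FBKO 2, taking 3 reads as the floor. These floors cover counting error only.

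Before the groups were compared, the replicates of a genotype were set against sampling noise with a chi-square test over genes with at least 10 reads in the pair. Chi-square per degree of freedom was 23.3 for the FLOXED pair and 17.4 for the PELP1 FBKO pair, so each library was counted as a separate sample. With at least 100 reads the values were 28.0 and 20.4. Between genotypes, the same ratio at 10 reads lay between 22.4 and 46.8.

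The main test was edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter, and a quasi-likelihood F test of genotype without further terms. It covered 14978 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.0201, a biological coefficient of variation of 14.2%. Standard errors of log2 fold changes were derived from the F statistic. Log2 fold changes are PELP1 FBKO minus FLOXED, and CPM values are TMM-scaled unless stated. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives, as were edgeR's exact test, other size factors, other count filters, a test against a 1.5-fold change, other thresholds, the replicate number as a block and leaving out each library in turn. Robust quasi-likelihood fitting, edgeR's newer quasi-likelihood method and per-library offsets for transcript length and GC content were added after seeing the data. Lengths and GC content came from the longest transcript of each gene in GENCODE vM21, and 98.9% of tested genes had them. That annotation belongs to a newer build than mm9, so no coordinates are given.

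Before the data were examined, 35 gene lists were written from general knowledge of the hippocampus, ischemic injury, estrogen and PELP1. They covered signaling and stress pathways, immune genes and markers of cell types, hippocampal fields and adjoining brain regions. Lists with at least 5 tested members were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over all lists. Estimated correlations and fry were alternatives. For each list the number of members past the threshold was also counted after adjustment over the list alone.

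The genes named were fixed by rule before the data were examined: Pelp1, the strongest genes past the threshold in each direction, the members of each list with the smallest p (up to 4), and Xist with Y-linked genes as a check of the animals' sex. With fewer than 5 genes past the threshold in a direction, the rule took the 5 with the smallest p, leaving out gene models without a proper name and small RNA genes. Not every gene the rule takes is reported here. Genes named outside this rule are said to have been chosen after their values were seen. In the RefSeq table of GRCm38, the spans of Alas2, Bop1, Car14, Cnp, Ogn, Uqcrq and Zic1 overlap another tested gene, so their counts are less certain where strand was not used.

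The procedure was tested on simulated data with the real means, library sizes and dispersions of 14978 genes, in 5 simulations of PELP1 FBKO against FLOXED with 200 genes changed. The main test recovered 70% of genes changed 2-fold and 95.4% of those changed 4-fold, and called 13.6 unchanged genes per simulation. DESeq2 recovered 69.8% and 88.0%, with 17.2 unchanged genes. Camera at the preset correlation found a list of 20 genes raised 1.5-fold in 5 of 5 simulations, and called 1 of 165 unchanged lists. With an estimated correlation it found that list in 0 of 5. The simulated genes varied independently, which genes in tissue need not do. In the real data the same test called 0 genes, with Padi2 at a 3.37-fold difference and an adjusted p of 0.0501. The recovered shares therefore describe the simulated counts and need not hold for the real libraries.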

Results

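Gene expression was measured in the mouse hippocampus after global cerebral ischemia (GCI), a transient stop of blood flow to the brain that injures CA1 pyramidal neurons. All animals were ovariectomized, received estradiol from mini pumps and were sampled at 24 h of reperfusion. FLOXED mice were compared with PELP1 FBKO mice, forebrain knockouts of the estrogen receptor co-regulator PELP1. Each genotype had 2 libraries, with between 17524594 and 22447658 reads assigned to genes. The comparison addresses which hippocampal transcripts differ between the genotypes in the injured, estradiol-treated brain. With no group free of ischemia or estradiol, a difference present before either cannot be told apart.

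Pelp1 itself, the targeted gene, was lower in both PELP1 FBKO libraries than in both FLOXED libraries. Its level was 26.5 ± 0.311 CPM (SD, n = 2) in FLOXED and 17.6 ± 0.470 CPM (SD, n = 2) in PELP1 FBKO, from 468, 569, 396 and 353 reads. The log2 fold change was -0.59 (SE 0.149), and Pelp1 did not pass the threshold over all genes (edgeR quasi-likelihood, adjusted p = 0.130). It passed with length and GC offsets (adjusted p = 0.0416), and the adjusted p ranged from 0.0416 to 0.345 over 15 alternatives. The counts cover the whole gene, and which part of it was deleted was not given in the sources used here. Xist, which is transcribed from the inactive X chromosome, lay between 234 and 401 CPM, unscaled by TMM, in the 4 libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in each library, which allows up to 0.171 CPM in the shallowest.

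The genes with the smallest p-values were mostly higher in PELP1 FBKO. Padi2, a peptidylarginine deiminase of oligodendrocytes, was at 40.7 ± 7.88 CPM (SD, n = 2) in FLOXED and 137 ± 6.93 CPM in PELP1 FBKO, with a log2 fold change of 1.75 (SE 0.162). Log2 fold changes were 1.58 (SE 0.168) for Id4, an inhibitor of DNA binding found in astrocytes, and 1.41 (SE 0.157) for Agt, the angiotensinogen gene, which astrocytes express. The carbonic anhydrase gene Car14 had 1.70 (SE 0.198). The complement gene C4b was at 53.2 and 76.1 CPM in FLOXED and at 201 and 248 CPM in PELP1 FBKO, and its counts are uncertain because it has a near-identical copy, C4a. On the lower side, Rprml was at 167 CPM in FLOXED and 70.8 CPM in PELP1 FBKO, a log2 fold change of -1.24 (SE 0.151). The glycogen-binding gene Stbd1 differed by -1.75 (SE 0.231), the kallikrein-related peptidase gene Klk7 by -2.85 (SE 0.374), and the interferon-induced genes Rsad2 and Ifi44 by -2.55 (SE 0.329) and -1.89 (SE 0.269). In each of these 10 genes both libraries of a genotype lay on the same side of both libraries of the other.

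None of these genes passed the threshold of 0.05. By edgeR's quasi-likelihood test 0 genes were higher and 0 lower, and the smallest adjusted p, 0.0501, was shared by 23 genes, 19 higher and 4 lower, among them the genes above except Ifi44 (0.0566). At an unadjusted p under 0.05 there were 2341 genes, 1509 higher and 832 lower, where 749 would be expected by chance. DESeq2 called 319 genes higher and 130 lower, edgeR's exact test 562 and 197, and limma-voom 0 and 0. Of the 293 genes with an edgeR adjusted p under 0.10, 234 were higher and 59 lower, and 263 of the 293 were called by DESeq2. The groups did not overlap in 48.4% of tested genes, against 33.3% by chance. The counts higher and lower were 317 and 216 without FLOXED 2, 457 and 104 without PELP1 FBKO 1, 274 and 324 without PELP1 FBKO 2, and 0 and 0 without FLOXED 1.

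**Figure D1:**
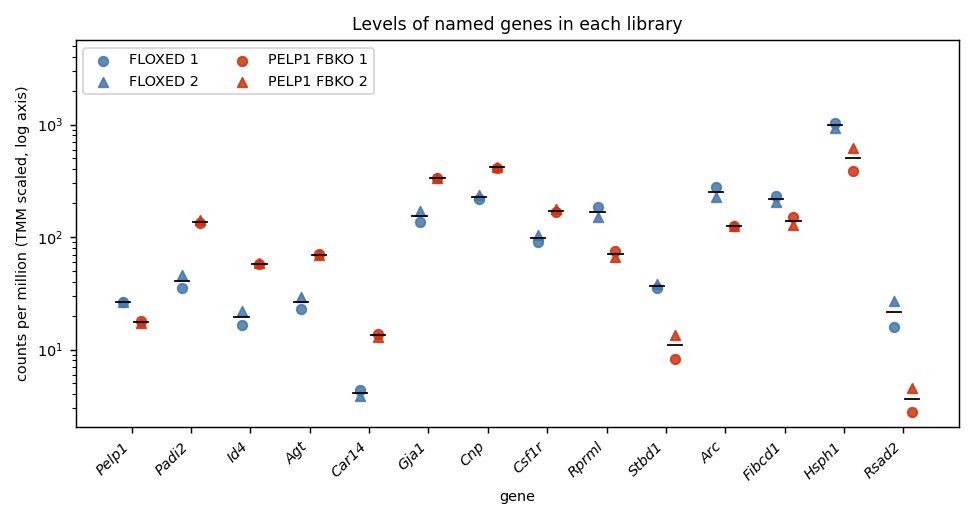
Levels of 14 named genes in CPM (TMM scaled, log axis), with a point for each library (blue FLOXED, red PELP1 FBKO, circles replicate 1, triangles replicate 2) and a line at each group's mean of 2 libraries. The 2 genotypes do not overlap in any of these genes, for example 35.1 and 46.3 against 132 and 142 for Padi2, and 26.7 and 26.2 against 17.9 and 17.3 for Pelp1.

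Of the 35 gene lists, 33 had enough tested members, and camera at the preset correlation called 22 of them, 11 higher and 11 lower in PELP1 FBKO. No member of any list passed the edgeR threshold over all genes. With an estimated correlation 0 lists passed, as with the directional fry test, while fry's mixed test passed 8. Those 8 were astrocyte, microglia, interneuron, CREB and Wnt lists, and ERK, antioxidant and neurogenesis lists, which camera had not called. Lists that the mixed test did not pass included those of oligodendrocytes (fry mixed adjusted p = 0.105), CA1 (0.155), cytokines (0.182) and interferon response (0.186). In the simulations, camera with an estimated correlation found the list of 20 genes raised 1.5-fold in 0 of 5. A list that camera misses with an estimated correlation may therefore still differ by that much. Larger differences, correlated members and the fry test were not simulated, so for these the simulations do not set the negative results aside. The preset test also called 16 lists when the 4 libraries were split by replicate number and 22 in the remaining split, which crosses the replicate numbers. The mean level of a list separated the genotypes in 21 of 33 lists, where chance would give 11. In 5 of them, those of astrocytes, oligodendrocytes, interneurons, PELP1 with ribosome biogenesis, and hypoxia, the gap between genotypes exceeded the largest difference within a genotype.

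**Figure D2:**
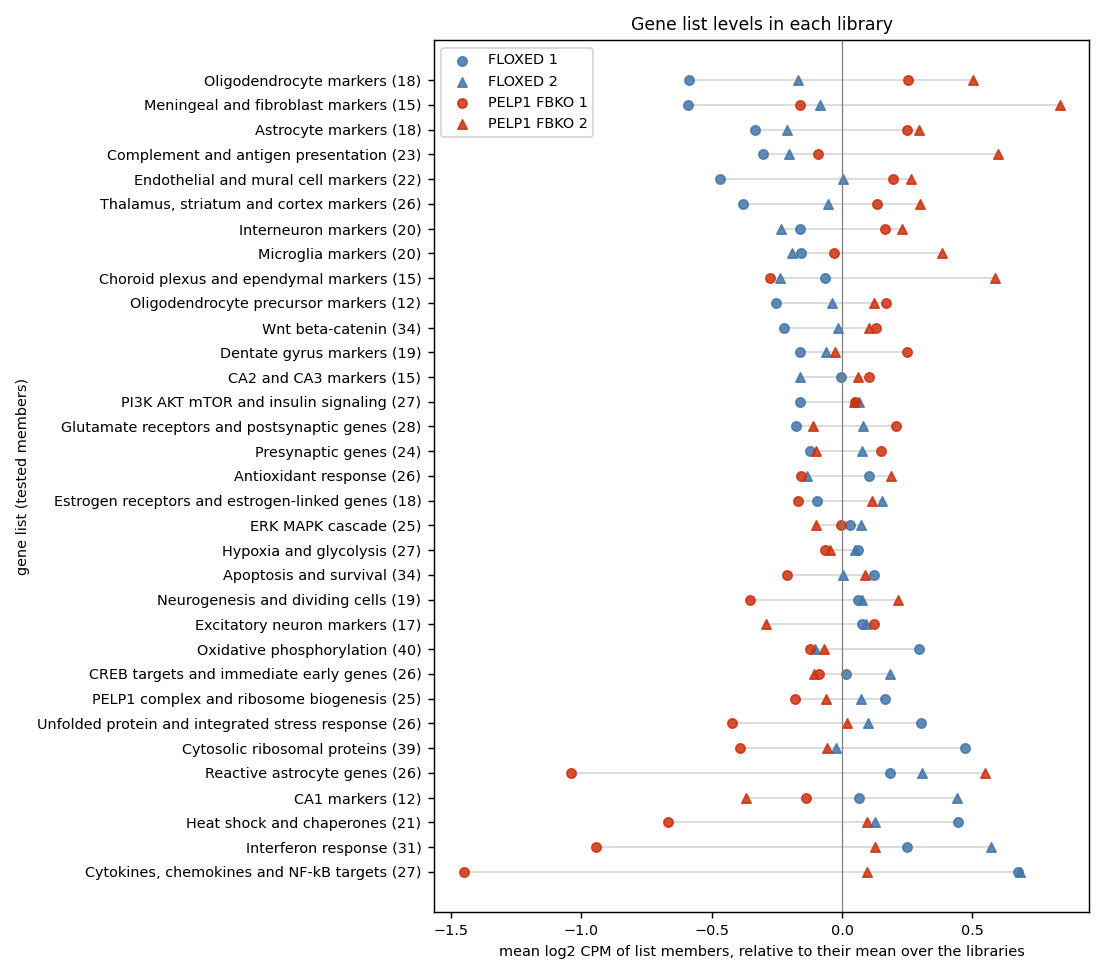
Mean log2 CPM of the tested members of each of 33 gene lists in each library, relative to the members' mean over the 4 libraries (horizontal axis, log2 units), sorted by the difference between genotypes (blue FLOXED, red PELP1 FBKO, circles replicate 1, triangles replicate 2). Astrocyte markers lay at 0.25 and 0.29 in PELP1 FBKO against -0.33 and -0.21 in FLOXED, while the cytokine list lay at -1.45 in PELP1 FBKO 1 but at 0.0964 in PELP1 FBKO 2.

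Markers of oligodendrocytes and astrocytes were higher in PELP1 FBKO. Of 18 oligodendrocyte markers 17 had a positive log2 fold change, with a mean of 0.74, and 14 were higher when adjusted over the list alone. Aspa, which encodes aspartoacylase, had a log2 fold change of 1.20 (SE 0.175), and the myelin genes Mog and Cnp had 0.87 (SE 0.135) and 0.87 (SE 0.137). Camera called this list (adjusted p = 6.48e-18, and adjusted p = 0.495 with an estimated correlation). All 18 astrocyte markers were on the higher side, with a mean of 0.54, and 11 were higher when adjusted over the list alone. Gja1, the gap junction gene of astrocytes, was at 137 and 171 CPM in FLOXED and at 338 and 338 CPM in PELP1 FBKO, a log2 fold change of 1.13 (SE 0.153), and the zinc transporter gene Slc39a12 had 1.05 (SE 0.152). The astrocyte list was called as well (adjusted p = 1.63e-14, and adjusted p = 0.428 with an estimated correlation). Oligodendrocyte precursor markers had a mean of 0.29, with 1 of 12 higher when adjusted over the list alone, the transcription factor gene Sox10 at 0.54 (SE 0.133). The precursor list was called (adjusted p = 0.00628, and adjusted p = 0.495 with an estimated correlation), but the call ended without FLOXED 1 (mean 0.187) and without PELP1 FBKO 1 (mean 0.241). The 26 genes of reactive astrocytes were not called (mean -0.25, adjusted p = 0.108). Here 0 members were past the threshold when adjusted over the list alone, 3 were higher and 0 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher. That list lay at -1.04 in PELP1 FBKO 1 and at 0.549 in PELP1 FBKO 2, and it was called higher without PELP1 FBKO 1 (mean 0.263), but lower without PELP1 FBKO 2 (mean -1.34) and by limma-voom (mean -0.516).

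Endothelial and microglial marker lists were also higher in PELP1 FBKO. All 22 endothelial and mural cell markers were on the higher side, with a mean of 0.435 and 4 higher when adjusted over the list alone. The transporter gene Slco1a4 of brain endothelium had a log2 fold change of 0.93 (SE 0.147), and Pdgfrb of pericytes had 0.65 (SE 0.189). Camera called this list (adjusted p = 1.53e-06, and adjusted p = 0.495 with an estimated correlation), with a mean of 0.233 without FLOXED 1 and 0.699 without FLOXED 2. Of 20 microglia markers 8 were higher and 1 lower when adjusted over the list alone, with a mean of 0.36. Csf1r, the receptor for colony-stimulating factor, had 0.81 (SE 0.135), and the cathepsin gene Ctss had 0.87 (SE 0.157). The microglia list was called (adjusted p = 4.92e-05, and adjusted p = 0.495 with an estimated correlation), but not without PELP1 FBKO 2 (mean 0.131). Of 23 complement and antigen presentation genes 4 were higher when adjusted over the list alone, with a mean of 0.52, and Cd74, the invariant chain gene, had 1.16 (SE 0.306). That call (adjusted p = 0.00044, and adjusted p = 0.552 with an estimated correlation) ended without PELP1 FBKO 2, where the mean was 0.113, and the mean was 0.798 without PELP1 FBKO 1. Meningeal and fibroblast markers had a mean of 0.74, with 4 of 15 higher when adjusted over the list alone, and Ogn, which encodes osteoglycin, had 1.17 (SE 0.182). Their call (adjusted p = 2.8e-05, and adjusted p = 0.495 with an estimated correlation) also ended without PELP1 FBKO 2 (mean 0.108), with the genotypes overlapping (-0.592 and -0.0828 in FLOXED, -0.16 and 0.834 in PELP1 FBKO), and the mean was 1.22 without PELP1 FBKO 1. Choroid plexus and ependymal markers were not called (mean 0.33, adjusted p = 0.0889), with 3 of 15 higher and 1 lower when adjusted over the list alone. They were called higher without PELP1 FBKO 1 (mean 0.516 over 18 members), by DESeq2 and with length and GC offsets (mean 0.328). The DESeq2 mean, 0.146, includes members that the count filter left out. Without PELP1 FBKO 2 the mean was -0.483. The 1 lower member was transthyretin (Ttr), a choroid plexus gene. It stood at 324 CPM in FLOXED 1, 67.5 in FLOXED 2, 21.4 in PELP1 FBKO 1 and 33.9 in PELP1 FBKO 2. Ttr does not stand for the list, where 11 of 15 members were on the higher side and 4 on the lower.

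Among neuronal markers, those of CA1 pyramidal cells were lower and those of interneurons higher in PELP1 FBKO. All 12 CA1 markers were on the lower side, with a mean of -0.52, and 6 were lower when adjusted over the list alone. The transcription factor gene Pou3f1 had a log2 fold change of -0.93 (SE 0.187), Fibcd1 -0.65 (SE 0.143) and Lefty1 -1.04 (SE 0.223). Camera called the CA1 list (adjusted p = 5.68e-07, and adjusted p = 0.495 with an estimated correlation), with a mean of -0.318 without FLOXED 2. Of 20 interneuron markers 8 were higher and 1 lower when adjusted over the list alone, with a mean of 0.40. Gad2, which encodes a GABA-synthesizing enzyme, had 0.64 (SE 0.149) and Reln, the reelin gene, had 0.74 (SE 0.173), while the neuropeptide gene Cck had -0.60 (SE 0.160). The interneuron list was called (adjusted p = 2.7e-06, and adjusted p = 0.495 with an estimated correlation). Dentate gyrus markers had a mean of 0.22, with 6 of 19 higher and 1 lower when adjusted over the list alone, Prox1 of granule cells at 0.93 (SE 0.196) and the desmoplakin gene Dsp at 0.95 (SE 0.218). Their call (adjusted p = 0.0206, and adjusted p = 0.567 with an estimated correlation) ended without PELP1 FBKO 1 (mean 0.055), and the mean was 0.351 without PELP1 FBKO 2. The 17 excitatory neuron markers had a mean of -0.165 and 0 members past the threshold when adjusted over the list alone, with 1 higher and 3 lower at an unadjusted p under 0.05 and 1 lower by DESeq2. Hpca, the hippocalcin gene, had -0.58 (SE 0.193). That list was called lower (adjusted p = 0.0325, and adjusted p = 0.661 with an estimated correlation), but its call ended without FLOXED 1 (mean -0.109), without FLOXED 2 (-0.096), without PELP1 FBKO 2 (0.104), with at least 50 reads in every library (-0.152) and with length and GC offsets (-0.185), and the mean was -0.406 without PELP1 FBKO 1. Markers of CA2 and CA3 were not called (mean 0.17, adjusted p = 0.109), with 2 of 15 higher when adjusted over the list alone, but were called higher without FLOXED 1 (mean 0.273), while the mean was 0.0978 without FLOXED 2 and 0.105 without PELP1 FBKO 1. Not called either were 28 glutamate receptor and postsynaptic genes (mean 0.10, adjusted p = 0.275) and 24 presynaptic genes (mean 0.04, adjusted p = 0.581), but the postsynaptic list was called higher without FLOXED 2 (mean 0.227) and without PELP1 FBKO 2 (mean 0.246), and the presynaptic list without PELP1 FBKO 2 (mean 0.161), while their means were -0.0915 and -0.108 without PELP1 FBKO 1. In both lists 0 members passed when adjusted over the list alone and DESeq2 called 0, with 3 postsynaptic members higher and 0 presynaptic members at an unadjusted p under 0.05.

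The lists of cytokine, interferon response and heat shock genes were lower in PELP1 FBKO and lowest in PELP1 FBKO 1. Cytokine, chemokine and NF-kB target genes had a mean log2 fold change of -1.15, with 11 of 27 lower when adjusted over the list alone. The chemokine gene Ccl2 was at 10.1 and 14.6 CPM in FLOXED and at 0.181 and 2.01 CPM in PELP1 FBKO. Lif, leukemia inhibitory factor, was at 16.2 and 25.1 against 1.81 and 7.79 CPM. Camera called this list (adjusted p = 2.28e-09, and adjusted p = 0.495 with an estimated correlation), with a mean of -0.696 without PELP1 FBKO 1 and -2.42 without PELP1 FBKO 2, but not over the 14 members with at least 50 reads in every library (mean -0.254). Of 31 interferon response genes 28 were on the lower side, with a mean of -0.74, and 2 (Rsad2 and Ifi44) were lower when adjusted over the list alone, while the regulator gene Irf7 had -1.62 (SE 0.457). With length and GC offsets 14 were lower and 2 higher over the list alone. The interferon list was called (adjusted p = 2.23e-09, and adjusted p = 0.528 with an estimated correlation), with a mean of -0.338 without PELP1 FBKO 1 and -1.42 without PELP1 FBKO 2. Heat shock genes and chaperones had a mean of -0.48, with 8 of 21 lower when adjusted over the list alone. Hsph1 was at 1040 and 923 CPM in FLOXED and at 386 and 622 CPM in PELP1 FBKO, and Hsp90aa1 had a log2 fold change of -0.72 (SE 0.152). This call (adjusted p = 2.45e-08, and adjusted p = 0.495 with an estimated correlation) went with means of -0.294 without FLOXED 1, -0.233 without PELP1 FBKO 1 and -0.98 without PELP1 FBKO 2. Unfolded protein and integrated stress response genes had a mean of -0.38, with 1 of 26 lower when adjusted over the list alone, the asparagine synthetase gene Asns at -0.84 (SE 0.163). Their list was called (adjusted p = 5.8e-06, and adjusted p = 0.495 with an estimated correlation), with a mean of -0.221 without PELP1 FBKO 1 and -0.647 without PELP1 FBKO 2.

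Hypoxia and glycolysis genes were slightly lower as a list, with a mean of -0.11 and 2 of 27 lower when adjusted over the list alone, among them Vegfa at -0.60 (SE 0.126). Members went both ways, 18 on the lower side and 9 on the higher. At an unadjusted p under 0.05, 4 were higher and 5 lower. Their call (adjusted p = 0.0325, and adjusted p = 0.495 with an estimated correlation) ended without FLOXED 1 (mean -0.0948), without FLOXED 2 (-0.118), without PELP1 FBKO 2 (-0.123) and with at least 50 reads in every library (-0.101). Antioxidant genes were not called (adjusted p = 0.804), and their median (-0.084) and mean (0.0456) differed in sign. There 3 of 26 were higher when adjusted over the list alone, including the quinone reductase gene Nqo1 at 1.21 (SE 0.216) and the peroxiredoxin gene Prdx6 at 0.66 (SE 0.172). With length and GC offsets 6 were higher and 4 lower over the list alone. Apoptosis and survival genes were not called either (mean -0.11, adjusted p = 0.109), but were called lower without PELP1 FBKO 2 (mean -0.285), while the mean was 0.0011 without PELP1 FBKO 1. Among them 0 of 34 passed when adjusted over the list alone, 2 were higher and 4 lower at an unadjusted p under 0.05, and DESeq2 called 0. The survival gene Bcl2 had 0.67 (SE 0.188) and the death effector gene Bax -0.60 (SE 0.200).

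Genes of ribosome production and of mitochondrial respiration were on the lower side as groups, with small differences per gene. PELP1 belongs to a complex that acts in ribosome maturation, and of 25 genes of that complex and of ribosome biogenesis 24 were on the lower side, with a mean of -0.24. Apart from Pelp1, the processing factor gene Rrp9 had -0.60 (SE 0.170) and Bop1 -0.45 (SE 0.152). In this list 0 members passed when adjusted over the list alone, 0 were higher and 4 lower at an unadjusted p under 0.05, DESeq2 called 0, and camera called it (adjusted p = 6.93e-05, and adjusted p = 0.495 with an estimated correlation). With length and GC offsets 6 members were lower when adjusted over the list alone. All 39 cytosolic ribosomal protein genes were on the lower side, with a mean of -0.47. Among them 0 passed when adjusted over the list alone, 8 were lower at an unadjusted p under 0.05, DESeq2 called 0, and Rps20 had -0.59 (SE 0.220). Camera called that list (adjusted p = 2.23e-09, and adjusted p = 0.535 with an estimated correlation), with a mean of -0.195 without FLOXED 1 and -0.703 without FLOXED 2. Of 40 oxidative phosphorylation genes 38 were on the lower side, with a mean of -0.21, and Uqcrq of complex III had -0.51 (SE 0.197). There 0 passed when adjusted over the list alone, 3 were lower at an unadjusted p under 0.05 and DESeq2 called 0. Camera called the list (adjusted p = 6.42e-05, and adjusted p = 0.661 with an estimated correlation), but the mean was 0.00786 without FLOXED 1, which ended the call, and -0.404 without FLOXED 2. Short transcripts moved with these groups. Across 14819 genes, which are not independent replicates, Spearman's correlation of transcript length was 0.241 with the log2 fold change between genotypes, -0.53 with the difference of FLOXED 1 from FLOXED 2, and 0.256 with that of PELP1 FBKO 1 from PELP1 FBKO 2.

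Among signaling lists, those of CREB targets and of Wnt genes were called. CREB targets and immediate early genes had a mean of -0.20, with 17 of 26 on the lower side and 9 on the higher, 4 lower when adjusted over the list alone, and a gap of 0.1 between genotypes against 0.169 within a genotype. Arc, a synaptic plasticity gene, was at 276 and 228 CPM in FLOXED and at 125 and 126 CPM in PELP1 FBKO, a log2 fold change of -1.01 (SE 0.145), and the neuronal pentraxin gene Nptx2 had -1.32 (SE 0.278). This list was called (adjusted p = 0.00159, and adjusted p = 0.495 with an estimated correlation), but not without FLOXED 2 (mean -0.109). Wnt and beta-catenin genes were called higher with a mean of 0.235 (adjusted p = 0.028, and adjusted p = 0.552 with an estimated correlation), and 5 of 34 were higher and 1 lower when adjusted over the list alone. The ligand gene Wnt5a had 0.81 (SE 0.176) and the receptor gene Fzd2 0.87 (SE 0.198), while Wnt2 had -1.78 (SE 0.291). That call ended without FLOXED 1 (mean 0.154), without PELP1 FBKO 1 (mean 0.238), by DESeq2 and with length and GC offsets (mean 0.164). The DESeq2 mean, 0.256, includes members that the count filter left out, and the mean was 0.417 without FLOXED 2. The lists nearest to rapid estrogen signaling did not pass the threshold in the main fit, but some alternatives called those of ERK and PI3K. The 25 ERK cascade genes had a mean of -0.11 (adjusted p = 0.059) and were called lower without FLOXED 1 (mean -0.122), without PELP1 FBKO 1 (mean -0.176) and with length and GC offsets (mean -0.157), but not without PELP1 FBKO 2 (mean -0.0587), with the feedback phosphatase gene Dusp6 at -0.53 (SE 0.138). For 27 genes of PI3K, AKT, mTOR and insulin signaling the mean was 0.09 (adjusted p = 0.282), called higher without FLOXED 2 (mean 0.211) but not without FLOXED 1 (mean -0.0072), with the binding protein gene Igfbp5 at 1.10 (SE 0.271) and Igf2 at 1.02 (SE 0.246). The 18 estrogen receptor and estrogen-linked genes had a mean of -0.02, against a camera direction of higher (adjusted p = 0.901), with Igf1 at 0.61 (SE 0.175). In each of these 3 lists 0 members passed when adjusted over the list alone. At an unadjusted p under 0.05 there were 0 higher and 4 lower ERK genes, 6 higher and 4 lower PI3K genes, and 3 higher and 1 lower estrogen genes, and DESeq2 called 0, 2 and 0 genes. With length and GC offsets, 3 ERK genes were lower over the list alone, 4 PI3K genes higher and 2 lower, and 1 estrogen gene lower.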

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

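The counts of genes depended on nearly every choice tried, and the cause was not tested. From 0 higher and 0 lower, they went to 13 and 4 with RLE size factors, 37 and 5 with upper-quartile scaling, 20 and 3 with library size alone, 319 and 130 with DESeq2, 278 and 81 without a filter, 39 and 4 with at least 50 reads in every library, and 562 and 197 with edgeR's exact test. Both stayed at 0 with limma-voom and against a 1.5-fold change. At a threshold of 0.10 they were 234 and 59, and at 0.01 they were 0. Leaving out a library, where the lone library is assumed to vary like the other group, gave 0 to 457 higher and 0 to 324 lower. Of 3 fits chosen after seeing the data, robust fitting gave 71 and 15, the newer quasi-likelihood method 20 and 4, and length and GC offsets 274 and 134. DESeq2 and the offsets shared 231 higher and 89 lower genes. Pelp1 stayed lower throughout, from -0.64 with length and GC offsets, where it passed, to -0.55 with upper-quartile scaling.

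With the replicate number as a replicate block there were 387 higher and 179 lower genes, but no label says that equal numbers pair samples. Across 14978 genes, which are not independent replicates, the difference of replicate 1 from 2 in FLOXED and in PELP1 FBKO correlated at -0.118 (Pearson) and -0.21 (Spearman). Under the block, the camera direction turned for the estrogen list (mean -0.0429) and the antioxidant list (mean 0.0327), neither of them called. The reactive astrocyte list was called lower there (adjusted p = 1.06e-05) and the choroid plexus list higher (adjusted p = 0.0379), while the hypoxia call ended (adjusted p = 0.06).

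Of 33 lists 22 were called at the preset correlation and 19 to 23 under the other fits, but 0 with an estimated correlation, 0 with directional fry and 8 with mixed fry. These were not the same lists throughout: the offsets called the ERK list (adjusted p = 0.0346) and the choroid plexus list (adjusted p = 0.0345), and ended the calls of Wnt genes (adjusted p = 0.0606) and excitatory neurons (adjusted p = 0.0735). With the offsets the direction turned for the estrogen list (-0.128), postsynaptic genes (-0.0191) and presynaptic genes (-0.0413). It also turned when a library was left out, with list means from -0.251 to 0.11 for estrogen, -0.0072 to 0.211 for PI3K, -0.149 to 0.174 for antioxidant, -1.34 to 0.263 for reactive astrocyte, -0.483 to 0.545 for choroid plexus, -0.406 to 0.104 for excitatory neuron, -0.0915 to 0.246 for postsynaptic, -0.108 to 0.161 for presynaptic and -0.46 to 0.189 for neurogenesis genes. Without a library, the list mean but not the camera direction changed sign for apoptosis (-0.285 to 0.0011) and oxidative phosphorylation genes (-0.404 to 0.00786). Of 65 named genes besides Pelp1, those that turned were Slc17a6, from -1.19 to 0.19 when a library was left out, and Ntng1, from -0.0933 to 0.121, and at -0.10 with the offsets. The depth limits genes with few reads in PELP1 FBKO, such as cytokine genes.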

Other observations

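The test of adjoining brain regions was set before its result per region was seen, though the result of the whole list was known, and the other tests of explanations here were chosen only after the results were seen. As a list, markers of brain regions next to the hippocampus were higher in PELP1 FBKO. Both PELP1 FBKO libraries were higher in 8 of 10 thalamic, 4 of 7 cortical and 2 of 9 striatal markers. Of 26 tested markers of thalamus, striatum and cortex 21 were on the higher side, with a mean log2 fold change of 0.42, and 5 were higher when adjusted over the list alone. The transcription factor gene Zic1 was at 3.48 and 4.84 CPM in FLOXED and at 10.3 and 30.0 CPM in PELP1 FBKO, and Synpo2 had a log2 fold change of 1.05 (SE 0.231). Camera called this list (adjusted p = 6.93e-05, and adjusted p = 0.495 with an estimated correlation).

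Genes of neurogenesis and dividing cells were not called as a list (mean -0.10, adjusted p = 0.109), though called lower without PELP1 FBKO 2 (mean -0.46, against 0.189 without PELP1 FBKO 1), and moved apart, with 4 of 19 higher and 3 lower when adjusted over the list alone. The doublecortin gene Dcx of immature neurons had a log2 fold change of 0.68 (SE 0.199), and the replication gene Mcm6 had -0.87 (SE 0.267). Too few blood-cell genes were measured for a list test. Of 20 leukocyte markers 4 were tested, with Lyz2 higher when adjusted over the list alone, at 1.13 (SE 0.282). The red blood cell gene Alas2, the only 1 of 10 tested, had 1.10 (SE 0.255).

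Glial, endothelial and interneuron lists were higher in PELP1 FBKO. A trend with transcript length and GC content is argued against, since each of the 4 lists kept at least 89.1% of its mean with the offsets. A smaller share of neurons of all types would lower interneuron markers. They were higher, by a gap of 0.327 between genotypes against 0.075 within a genotype. That rise is part of the pattern and was seen before the test was chosen, so it is no separate test. A smaller share of excitatory neurons stays open. Oligodendrocyte markers exceeded precursor markers by 0.457, with a gap of 0.219 against 0.292 within a genotype. Excitatory markers were lower in PELP1 FBKO 2 (-0.291) but not in PELP1 FBKO 1 (0.122, against 0.0757 and 0.0936 in FLOXED). That value goes against a fall of excitatory neurons in general in that library. CA1 markers were lower in both (-0.137 and -0.369, against 0.0652 and 0.441 in FLOXED). Dentate gyrus markers were higher in both (0.248 and -0.0271, against -0.16 and -0.061 in FLOXED). The gap between genotypes was 0.202 for CA1 markers, against 0.376 within a genotype. For dentate gyrus markers it was 0.0339 against 0.275, and their mean was 0.055 without PELP1 FBKO 1. These lists of excitatory cells went opposite ways, but neither gap exceeded the difference within a genotype. More tissue from adjoining regions in the PELP1 FBKO samples stays open and may contribute: 8 of 10 thalamic markers (80%) were higher in both PELP1 FBKO libraries, against 57.1% for cortex, 22.2% for striatum and 25.4% of all tested genes, among them the abundant Calb2 (62.4 and 41.8 CPM in FLOXED, 70.0 and 108 in PELP1 FBKO) but not Ntng1 (35.9, 41.9, 37.7 and 41.0 CPM) and Slc17a6 (13.5, 35.3, 14.0 and 17.1 CPM), Ntng1 being chosen after its values were seen. All 10 thalamic markers had a mean of at least 1 CPM in FLOXED and 4 stand in another list, and an effect of genotype on these cells stays open and untested. Whether tissue from adjoining regions also bears on the lower CA1 markers was not tested.

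Cytokine, interferon and chaperone lists were lower in PELP1 FBKO. The length and GC trend is argued against, since each list kept at least 102% of its mean with the offsets. Fewer microglia as the whole source would lower their markers by at least 0.476, the smallest of the list differences. The lower PELP1 FBKO library lay 0.619 above that level, against 0.414 within a genotype (mean 0.362, and 0.131 without PELP1 FBKO 2). These levels were seen before the test was chosen, so it is no separate test. They argue against fewer microglia only as far as marker levels follow cell number, which was not measured. Fewer blood-borne leukocytes, with 4 tested markers, stay open. For cytokine genes, PELP1 FBKO 2 lay 0.577 lower than FLOXED libraries that differed by 0.011 (by at most 0.509 in any of 33 lists). That goes against PELP1 FBKO 1 alone as the whole source. It rests on 1 library, however, and the PELP1 FBKO libraries differed by 1.55. The mean was only -0.254 over members with at least 50 reads in every library. PELP1 FBKO 1 alone is therefore not excluded for cytokine genes. It stays open for interferon genes (0.121 lower against 0.323) and heat shock genes (0.0323 lower against 0.315). Without PELP1 FBKO 1 the list means were -0.696, -0.338 and -0.233, without PELP1 FBKO 2 they were -2.42, -1.42 and -0.98, and heat shock genes averaged -0.294 without FLOXED 1; a difference between animals in the severity of ischemia stays open beside an effect of genotype, neither of them tested.

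Ribosomal protein and oxidative phosphorylation lists were lower in PELP1 FBKO. For ribosomal proteins 82.7% of the mean was kept with the offsets. Those offsets used the longest transcript of each gene, which need not be the form expressed. They may therefore undercorrect short transcripts, and the length and GC trend stays open for ribosomal proteins. FLOXED 1 alone stays open for them, since FLOXED 2 lay at -0.0215, PELP1 FBKO 2 at -0.0587 and PELP1 FBKO 1 at -0.391, a gap of 0.0372 while the PELP1 FBKO libraries differed by 0.332, with a mean difference of -0.195 without FLOXED 1 and -0.703 without FLOXED 2. For oxidative phosphorylation 61.9% was kept with the offsets, but FLOXED 2, at -0.104, lay between the PELP1 FBKO libraries (-0.122 and -0.07), a gap of -0.034, and the mean without FLOXED 1 was 0.00786, so that library may be the source of that difference (-0.404 without FLOXED 2). An effect of genotype on ribosomal protein genes stays open and untested.

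The 4 libraries allow 3 splits into equal groups, too few for a share under 0.05. The split by genotype gave 2341 genes at an unadjusted p under 0.05, and the highest of the other splits gave 449. The genotype count was reached in 1 of the 3 splits, the genotype split itself. Other measures did not set genotype apart. Each split gave 0 genes past the adjusted threshold. Camera at the preset correlation called 22 lists by genotype, 16 by replicate number and 22 in the crossed split.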
